A study of Homo sapiens with 9 samples.

How the data were processed

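Polyadenylated RNA from frozen sections of 9 A375 xenografts was made into TruSeq libraries and sequenced in pairs of reads, per the labels' protocols. The authors deposited a table of raw counts of reads per human Ensembl gene, with 60386 genes and 9 columns, and 5 tables of their own comparisons, each of a single resistant tumour with the 4 untreated tumours. STAR 2.3.0.1, HTSeq 0.5.3, DESeq 1.18.0 and GSNAP, and the human build GRCh37 (hg19) and the mouse build GRCm38 (mm10), are named in the submitters' processing notes, with no role or order. How reads of mouse cells were set aside, and whether counting used the strand, is not given in the sources used here, so reads of overlapping or antisense genes and of close relatives cannot be told apart.

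Per the file headers, the authors' deposited tables give a mean signal over 5 libraries and in each arm, a fold change (ratio), its log2 value with a moderated version, and a p-value with its adjusted p-value. The relation of the 3 means was checked and held for every tested gene. The resistant tumour's values in the authors' deposited tables were whole multiples of a fixed step for 99.65 to 100% of genes, within a tolerance of 0.01 of a step. They were not the raw counts times a constant. Over genes with at least 50 counts, the ratio of table to count had medians from -0.28 to 0.38 on the log2 scale between bins of genes by GC content. The step that changed the counts is not given in the sources used here. Of the values in these tables, the counts of calls and the fold changes were set beside the new fits. The tables list an interval of 110 bp in the median for tested protein-coding genes, which is not the extent of a gene, so no gene start or end is printed. Chromosome names, gene symbols and the interval starts that placed genes in chromosome windows were also taken from them.

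Samples were grouped by the labels' treatment: 4 untreated tumours and 5 tumours that grew under vemurafenib at 120 mg/kg until day 39. Replicate numbers follow the order of the records and pair nothing. The labels give no batch. They do not say whether each tumour came from a separate mouse, so p-values measure the spread between these tumours. Total counts ranged from 15134791 to 34915366 per library. A count of 0 allows up to 3 reads, or 0.0854 to 0.197 CPM depending on the library. Intervals and such floors cover counting error only, since reads carried no molecular identifiers.

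Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test (estimateDisp, glmQLFit and glmQLFTest at default settings, TMM normalization, filterByExpr on the 2 groups), with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values use the TMM library sizes. The SE of a log2 fold change is the fold change divided by the square root of its F statistic, an approximation. Single tumours were fitted as levels of their own and are assumed to vary as the other groups do. Resistant libraries were less alike than untreated ones, so this is not borne out where the spread came from untreated tumours. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and an inter-gene correlation preset at 0.01, with adjustment over the lists. Library measures and marker scores (the mean log2 CPM of a list's tested members) were compared by two-sided exact permutation over all splits of the samples into groups of these sizes.

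The tests, the gene lists and the rule for naming genes were fixed before the data were examined. The rule takes the 12 highest and 12 lowest log2 fold changes among called genes with a mean of at least 5 CPM in a group and no overlap between groups, a set of pathway genes named whatever their values (some of these are not reported here), up to 4 members of each list with the smallest p, and for each resistant tumour the 3 highest and 3 lowest called genes against the other resistant tumours. Genes with clone names were counted and not named; 451 of them were called in the comparison of the groups. The lists cover ERK output, pathway components, receptors and ligands, melanocyte lineage, the undifferentiated melanoma state, cell cycle, interferon response, antigen presentation, hypoxia and glycolysis, oxidative phosphorylation, cholesterol synthesis, unfolded protein and amino acid stress, p53 targets, the BCL2 family, NF-kB and cytokines, TGF-beta and matrix, drug transport, mitochondrial transcripts, and markers of 7 other cell types. Their members were matched by symbol on the main chromosomes, where PECAM1 had no match.

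Alternatives were other size factors, library sizes without mitochondrial and the 10 most abundant genes, other filters, DESeq2 1.42.0, limma-voom with sample weights, robust fitting, stricter thresholds, an estimated correlation, another prior count and leaving out each library. A correction for GC content was added after seeing the data: each library's loess trend (span 0.3) of log2 CPM with GC content, taken from GENCODE transcripts matched by gene identifier for 97.4% of tested genes, entered as an offset. The fits were tested on simulated data drawn from the real means, library sizes and dispersions with 200 changed genes. Each gene had the same dispersion in all libraries, taken from the fit of the 2 groups. The unequal spread of untreated and resistant tumours was therefore not simulated, and false calls from it are not covered. For resistant against untreated, 64% of genes changed 2-fold and 86% of genes changed 4-fold were recovered among 16436 genes, with 7 false calls. For resistant tumour 4 against untreated these shares were 3% and 43% among 16442 genes, and against the other resistant tumours 20% and 64% among 16450 genes. In the list test, the changed list was called and 0 of 20 unchanged lists were, over 16655 genes. Genes were simulated independently, so this does not show how often lists of correlated genes are called falsely. In the real lists called, the estimated correlation was 0.067 to 0.87.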

Results

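RNA was sequenced from xenograft tumours of A375, a human melanoma cell line with an activating BRAF mutation, grown in mice. Vemurafenib is a kinase inhibitor that blocks mutant BRAF, the kinase that drives MEK and ERK signalling in such cells. The data held 5 tumours from mice given vemurafenib at 120 mg/kg until day 39, by which time the tumours had become resistant, and 4 untreated tumours. The deposited table gave read counts for 60386 human genes. The totals ranged from 16155842 to 30959418 reads in the untreated tumours and from 15134791 to 34915366 in the resistant tumours, and 16655 genes had enough reads to be tested. Libraries of untreated tumours correlated at 0.986 to 0.994 with each other across genes, and those of resistant tumours at 0.938 to 0.978. No pair of libraries agreed within sampling noise. Levels are given in CPM, reads scaled to a common library size, with the SD over 4 untreated or 5 resistant tumours. Positive log2 fold changes mean higher in resistant tumours. The comparison asked which genes differed once tumours grew under the drug, and drug exposure, day of collection and resistance cannot be separated in this design.

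Genes whose transcription follows ERK activity fell as a group in the resistant tumours. DUSP6, a phosphatase induced by ERK that acts back on it, fell from 442 ± 24.8 to 59.1 ± 35.8 CPM (log2 fold change -2.90, SE 0.39, edgeR adjusted p = 0.00061). SPRY4, another feedback inhibitor of the pathway, went from 447 ± 42.1 to 51.5 ± 53.1 CPM (log2 fold change -3.11, SE 0.57, edgeR adjusted p = 0.0034). It was at 145 CPM in resistant tumour 4 and at 18.9 to 42.3 CPM in the other resistant tumours. The early response gene EGR1 went from 98.0 ± 17.1 to 7.64 ± 4.06 CPM, and the chromatin protein gene HMGA2 from 923 ± 52.3 to 325 ± 41.5 CPM. DUSP4, ETV4, ETV5, CCND1, EPHA4 and SPRED2 were also called lower, with log2 fold changes of -1.29, -1.52, -0.86, -1.16, -2.41 and -0.82. Of the 29 members of the list, 23 fell, 1 rose and 5 were not called. Adjusted over the list alone, 25 fell and 1 rose. The member that rose, named here after its values were seen, was the receptor gene EPHA2 (log2 fold change 1.12). The list moved down relative to other genes (camera adjusted p = 4.98e-12), a call that was lost with an estimated correlation between genes (camera adjusted p = 0.562).

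**Figure D1:**
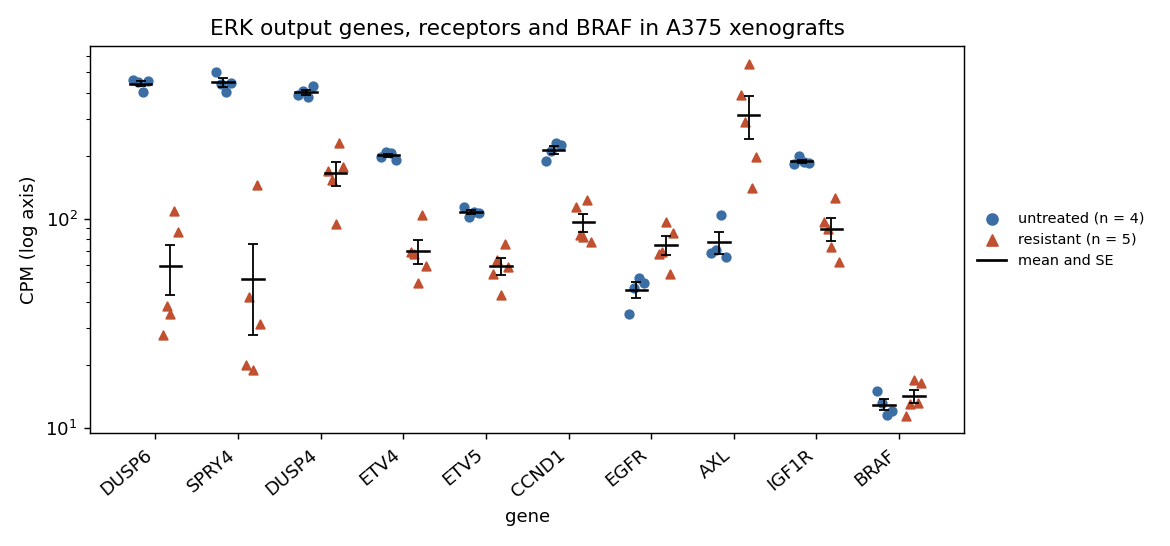
Levels in CPM on a log axis for 10 genes in 4 untreated tumours (circles) and 5 resistant tumours (triangles), with each group's mean and SE as a line and bars. All 5 resistant tumours lie below all 4 untreated tumours for DUSP6, SPRY4, DUSP4, ETV4, ETV5, CCND1 and IGF1R, and above them for EGFR and AXL.

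The largest rises among named genes started from almost no reads in untreated tumours. MKX, a homeobox transcription factor gene, was at 0.063 ± 0.13 CPM in untreated and 58.3 ± 58.4 CPM in resistant tumours. LIPG, which encodes endothelial lipase, had 3 reads over the untreated libraries and 4295 over the resistant ones, a ratio of 1080 with a 95% counting interval of 370 to 5260. The keratin genes KRT75 and KRT5 reached 40.9 ± 42.7 and 12.2 ± 7.36 CPM. The matrix crosslinking enzyme gene LOXL1 reached 39.7 ± 15.5 CPM from 0.42 ± 0.15 CPM, and the peptidase gene MME reached 64.8 ± 37.6 CPM from 1.02 ± 1.17 CPM. PIK3C2G, GALNTL2, SDPR, PAMR1, AMPH and TEK completed the 12 highest, with log2 fold changes from 6.24 to 7.50. PIK3C2G was at 0.38 CPM in resistant tumour 1 and at 60 CPM in resistant tumour 5.

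HMP19 had 1737 reads over the untreated libraries and 0 over the resistant libraries, at least 765-fold lower against a floor of 3 reads over the group. The chemokine gene CXCL11 had 920 reads in untreated and 3 in resistant tumours, a ratio of 405 with a 95% counting interval of 138 to 1970. CXCL10 went from 8.20 ± 4.67 to 0.33 ± 0.47 CPM. NPTX2, a neuronal pentraxin gene, went from 409 ± 60.8 to 11.9 ± 12.6 CPM, and SORCS1 from 168 ± 19.4 to 7.88 ± 10.6 CPM. SORCS1 was at 25.1 CPM in resistant tumour 4 and at 0.09 to 11.1 CPM in the other resistant tumours. The receptor subunit genes GABRR1 and CHRNA1 and the mucin gene MUC6 had log2 fold changes of -6.08, -4.69 and -4.45. FIBCD1, ATP6V0A4, GPRIN3 and PRRX2 were the other members of the 12 lowest, with log2 fold changes of -5.77, -4.72, -4.68 and -4.51.

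Components of the pathway upstream of ERK moved both ways or were not called. BRAF was at 12.9 ± 1.59 CPM in untreated and 14.2 ± 2.32 CPM in resistant tumours (log2 fold change 0.13, SE 0.14, edgeR adjusted p = 0.534). NRAS, MAP2K2 and NF1 were not called, with log2 fold changes of 0.06, 0.20 and 0.32. MAP2K1, which encodes MEK1, fell from 105 ± 5.66 to 80.2 ± 8.52 CPM (edgeR adjusted p = 0.0103). RASA2, KSR2 and HRAS fell by 1.08, 2.298 and 0.41 on the log2 scale. MAP3K8 had 1 to 32 reads per library and was not tested. Of 22 tested components, 3 rose, 4 fell and 15 were not called, with 3 and 4 adjusted over the list alone (camera adjusted p = 0.777). These are transcript levels and carry no information on mutations or splice forms.

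Receptor tyrosine kinases and their ligands moved both ways. AXL rose from 77.1 ± 18.1 to 314 ± 163 CPM (log2 fold change 2.03, SE 0.37, edgeR adjusted p = 0.00337). EGFR rose from 45.7 ± 7.58 to 74.8 ± 16.6 CPM (log2 fold change 0.71, SE 0.18, edgeR adjusted p = 0.0142). The ligand genes KITLG and PDGFC rose by log2 fold changes of 4.12 and 1.49, with KITLG at 1.42 ± 0.084 CPM in untreated and 24.8 ± 6.48 CPM in resistant tumours. TGFA, an EGFR ligand gene, fell from 105 ± 18.3 to 6.64 ± 4.74 CPM, and FGFR1 from 256 ± 15.9 to 73.7 ± 20.7 CPM. IGF1R fell by 1.07 on the log2 scale. PDGFRB and MET were not called, at log2 fold changes of 0.15 and 0.30. In all, 10 of 33 tested members rose, 8 fell and 15 were not called. Adjusted over the list alone, 11 rose and 12 fell (camera adjusted p = 0.993).

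Levels of SOX10 and ERBB3 were far apart among the resistant tumours. SOX10, a melanocyte lineage transcription factor gene, was at 163 ± 17.95 CPM in untreated tumours and at 14.8, 137, 5.46, 231 and 22.6 CPM in resistant tumours 1 to 5. ERBB3 was at 173 ± 21.97 CPM in untreated tumours and at 6.25, 129, 11.3, 255 and 26.8 CPM in the same 5 tumours. Neither was called as a group difference (edgeR adjusted p = 0.421 and 0.420). MITF was at 20.8 ± 2.67 and 42.7 ± 27.5 CPM (edgeR adjusted p = 0.0585), with 90.3 CPM in resistant tumour 4. It was at 24.1 to 41.0 CPM in the other resistant tumours and at 17.6 to 24.0 CPM in untreated ones. Of 20 alternative settings, MITF was called in 5, and SOX10 and ERBB3 in 1 each. NGFR was at 10.1 ± 2.46 and 30.5 ± 44.8 CPM (edgeR adjusted p = 0.175), with 110 CPM in resistant tumour 2. LEF1 and S100A1 had log2 fold changes of -3.28 and -2.295, and SNAI2 and PPARGC1A rose by 2.18 and 1.92. Of 24 tested members of the melanocyte lineage list, 3 rose and 4 fell, or 7 and 4 adjusted over the list alone (camera adjusted p = 0.832). Of 32 tested genes of the undifferentiated melanoma state, 11 rose and 7 fell by both adjustments, that over all genes tested and that adjusted over the list alone (camera adjusted p = 0.504). LOXL2 rose to 163 ± 22.1 CPM from 70.8 ± 8.57 CPM, while INHBA, PLAUR and TWIST1 fell by 3.46, 1.37 and 1.19 on the log2 scale.

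**Figure D2:**
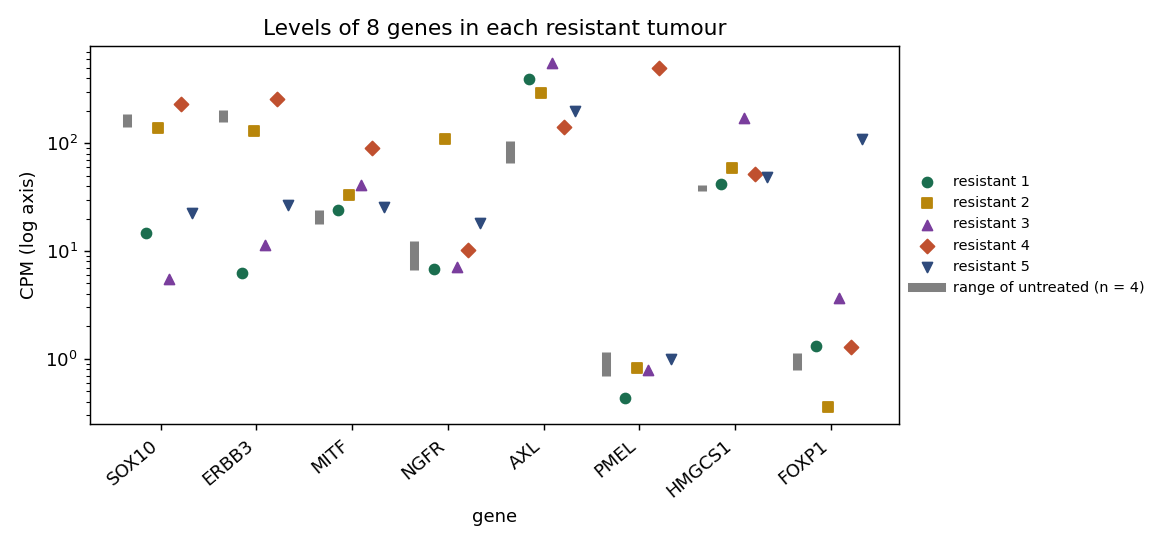
Levels in CPM on a log axis for 8 genes, with each of the 5 resistant tumours as its own symbol and the range of the 4 untreated tumours as a grey bar. PMEL reaches 501.8 CPM in resistant tumour 4, FOXP1 109 CPM in resistant tumour 5, and SOX10 ranges from 5.46 to 231 CPM.

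Cell cycle genes rose. Of 32 tested, 22 rose, 0 fell and 10 were not called, and 26 rose adjusted over the list alone (camera adjusted p = 3.66e-07, and 0.562 with an estimated correlation). MCM5 and MCM6, subunits of the replicative helicase, had log2 fold changes of 0.85 and 0.67, and TK1 and CDC6 of 1.10 and 0.76. The proliferation marker gene MKI67 went from 191 ± 7.20 to 317 ± 119 CPM (log2 fold change 0.73, SE 0.24, edgeR adjusted p = 0.0465), with 171 CPM in resistant tumour 4. Leaving out any library but resistant tumour 4 ended the MKI67 call, with edgeR adjusted p of 0.0542 to 0.107, as did robust fitting (edgeR adjusted p = 0.0536).

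Genes of nuclear-encoded respiratory chain subunits rose, 17 of 31, with 0 lower and 14 not called, and 18 adjusted over the list alone (camera adjusted p = 7.75e-05, and 0.562 with an estimated correlation). ATP5B rose from 777 ± 17.3 to 1136 ± 98.1 CPM, and SDHA, UQCRC1 and NDUFV2 had log2 fold changes of 0.53, 0.42 and 0.71. Transcripts of the mitochondrial genome fell, 7 of 12, and 11 adjusted over the list alone (camera adjusted p = 0.000695, and 0.562 with an estimated correlation). MT-ND6 and MT-ND1 fell by 0.87 and 0.75 on the log2 scale, and MT-ND3 and MT-ND5 by 0.57 and 0.44. They made up 3.78 ± 0.35% of reads in untreated and 2.96 ± 0.50% in resistant tumours (two-sided exact permutation p = 0.0397, adjusted over 9 library measures 0.0893).

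Of 30 genes of hypoxia and glycolysis, 14 rose and 6 fell, or 15 and 6 adjusted over the list alone (camera adjusted p = 0.0434, and 0.562 with an estimated correlation). PKM, a pyruvate kinase gene, rose from 2848 ± 95.7 to 4168 ± 289 CPM. CA12 and PFKP rose by log2 fold changes of 2.64 and 0.67, while PFKFB3 fell by 1.45 on the log2 scale. The list's call was lost without untreated tumour 3 or 4 or without resistant tumour 1, 3 or 4, at camera adjusted p up to 0.128. Of 23 tested p53 targets, 14 rose and 2 fell, or 15 and 3 adjusted over the list alone (camera adjusted p = 0.000583, and 0.562 with an estimated correlation). CDKN1A, a cell cycle inhibitor gene, rose from 46.9 ± 10.5 to 150 ± 37.0 CPM, DDB2 and BAX had log2 fold changes of 1.08 and 0.52, and AEN fell by 0.72 on the log2 scale. In the BCL2 family, MCL1, which protects from apoptosis, fell from 590 ± 45.3 to 334 ± 24.7 CPM, and the death-promoting genes BBC3, BAX and BID rose by 1.63, 0.52 and 0.41 on the log2 scale. Of its 17 tested members, 5 rose and 4 fell, or 5 and 6 adjusted over the list alone (camera adjusted p = 0.938).

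Interferon response genes were lower as a list (camera adjusted p = 0.00264, and 0.774 with an estimated correlation), though 4 of 29 members fell and 25 were not called. The 4 members were CXCL10, CXCL11, IDO1 and STAT2, the last pair with log2 fold changes of -3.70 and -0.86. Adjusted over the list alone, 3 fell. Among all 16655 tested genes 2428 were called lower, a share similar to 4 of 29. The list's mean log2 fold change was -1.08 and its median -0.52, with CXCL11, CXCL10 and IDO1 the lowest members. Of 24 antigen presentation genes, 8 fell and 0 rose by both adjustments, that over all genes and that adjusted over the list alone (camera adjusted p = 0.0199, and 0.774 with an estimated correlation). HLA-B went from 530 ± 252 to 177 ± 77.6 CPM, and HLA-DRB1, HLA-DRA and HLA-DPA1 fell by 3.42, 2.37 and 0.64 on the log2 scale. HLA genes share sequence, and the table lists copies on alternate haplotypes, so these counts are uncertain. The antigen presentation call was lost without untreated tumour 1 (camera adjusted p = 0.0837) or resistant tumour 4 (camera adjusted p = 0.128). That of STAT2 was lost without any untreated tumour or resistant tumour 3 or 5 (edgeR adjusted p 0.0507 to 0.0937), and that of HLA-DRA without untreated tumour 1 (edgeR adjusted p = 0.0528).

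The other lists were not called. Of 19 tested NF-kB and cytokine genes, 3 rose and 6 fell, or 3 and 9 adjusted over the list alone (camera adjusted p = 0.259). TNFAIP2, NFKBIA and SOD2 rose by log2 fold changes of 2.20, 0.55 and 0.65, and IL11 fell by 0.86 on the log2 scale. Of 37 TGF-beta and extracellular matrix genes, 11 rose and 10 fell, or 11 and 13 adjusted over the list alone (camera adjusted p = 0.993). LTBP1, a TGF-beta binding protein gene, rose from 6.78 ± 1.86 to 130 ± 69.7 CPM, whereas MMP13 fell from 62.6 ± 16.8 to 5.45 ± 2.90 CPM and TIMP1 from 451 ± 71.8 to 128 ± 31.4 CPM. Of 23 cholesterol synthesis genes, 3 rose and 1 fell by both adjustments, also adjusted over the list alone (camera adjusted p = 0.0646). MVK, EBP and CYP51A1 rose by 0.85, 0.52 and 1.28 on the log2 scale, and TM7SF2 fell by 0.83. Of 24 genes of unfolded protein and amino acid stress, 3 rose and 6 fell by both adjustments, also adjusted over the list alone (camera adjusted p = 0.0974). SLC7A11, a cystine transporter gene, fell from 29.2 ± 10.0 to 4.36 ± 0.58 CPM, EDEM1 and XBP1 fell by 0.79 and 0.60, and PSAT1 rose by 0.58 on the log2 scale. Of 12 drug transport and metabolism genes, 3 rose and 2 fell, or 3 and 3 adjusted over the list alone (camera adjusted p = 0.938). The efflux pump genes ABCG2, ABCC1 and ABCC3 rose by 1.79, 0.59 and 1.13 on the log2 scale, and AHRR fell by 1.09. Calls were lost for CYP51A1 and ABCC3 without untreated tumour 1, 2 or 3, for EBP without untreated tumour 2 or 4 and for AHRR without untreated tumour 4, at edgeR adjusted p of 0.0519 to 0.0706.

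**Figure D3:**
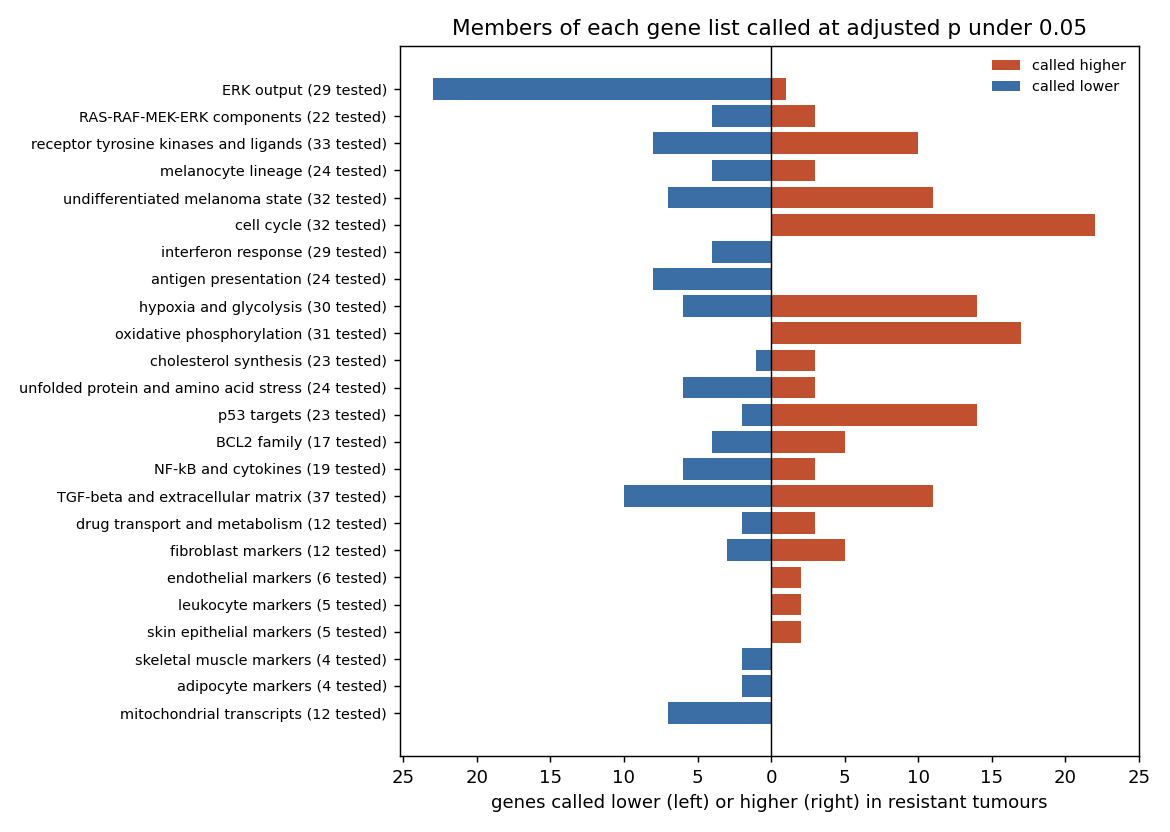
Number of members of each gene list called lower (bars to the left) or higher (bars to the right) in 5 resistant against 4 untreated tumours by edgeR, with the number of tested members after each list's name. ERK output shows 23 lower and 1 higher, and the cell cycle list 22 higher and 0 lower.

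Markers of other cell types moved in different directions. How reads of mouse cells were set aside is not given in the sources used here, so these values can include reads of host cells. Of 12 tested fibroblast markers, 5 rose and 3 fell by both adjustments, also adjusted over the list alone (camera adjusted p = 0.430). COL1A1 rose from 450 ± 215 to 2459 ± 582 CPM and COL3A1 from 184 ± 66.8 to 728 ± 156 CPM, while LUM and PDGFRA fell by 2.56 and 2.77 on the log2 scale. TEK and TIE1 rose among 6 endothelial markers, with 2 rising and 2 falling adjusted over the list alone (camera adjusted p = 0.993). CSF1R and EMR1 rose among 5 leukocyte markers, with 2 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.777). KRT5 and SFN rose among 5 skin epithelial markers, with 3 rising adjusted over the list alone (camera adjusted p = 0.201). TNNT3 and NEB fell among 4 skeletal muscle markers and CIDEC and PLIN4 among 4 adipocyte markers, with the same counts adjusted over the list alone (camera adjusted p = 0.138 and 0.0646). Calls were lost for TIE1 without untreated tumour 2, EMR1 without untreated tumour 2, 3 or 4, NEB without any untreated tumour or resistant tumour 3 or 5, and PLIN4 without untreated tumour 2, 3 or 4 or resistant tumour 1, 2 or 3 (edgeR adjusted p 0.0521 to 0.110). NEB and PLIN4 were also not called without a filter on low counts (edgeR adjusted p = 0.0549 and 0.0567). No erythroid marker had enough reads to be tested. In mean log2 CPM, the skin epithelial score was higher by 1.41 and the skeletal muscle and adipocyte scores differed by -1.34 and -1.19 (two-sided exact permutation p = 0.00794, 0.0159 and 0.00794, adjusted 0.0357, 0.0476 and 0.0357), where 0.00794 is the smallest p that splits of 9 tumours into 4 and 5 can give. Leaving out any library ended these 3 calls (two-sided exact permutation adjusted p 0.0643 to 0.107). With fewer splits the smallest p possible is higher, which alone can end a call. These losses therefore do not show that a score rests on any single library. The 3 scores rest on 5 of 14, 4 of 14 and 4 of 10 listed markers, and members differed within each. KRT5, TNNT3 and CIDEC had log2 fold changes of 6.52, -3.43 and -3.88. DSP, TNNC2 and LIPE of the same lists were not called, at -0.76, 0.05 and -0.14. The signs of the median, the mean and the camera test did not match within the lists of pathway components, receptors, melanocyte lineage, BCL2 family, matrix, drug transport and endothelial genes.

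Over all tested genes, 2433 were higher and 2428 lower in resistant tumours by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. At least 2-fold changes were found for 907 of the higher and 824 of the lower genes. The 2 groups did not overlap for 28.1% of tested genes, where chance gives 1.59%. Requiring an adjusted p under 0.01 left 1125 and 1232 genes.

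Each resistant tumour was also set against the 4 untreated tumours, as in the authors' own tables. These fits assume that a resistant tumour varies as an untreated one does. Resistant libraries correlated at 0.938 to 0.978 with each other and untreated ones at 0.986 to 0.994, so the assumption is not borne out. The p-values can be too small and the counts too high, and the counts do not measure resistance. In edgeR, resistant tumours 1 to 5 had 4259, 3474, 6107, 2700 and 4277 genes called. The authors' deposited tables call 4355, 3705, 5435, 2948 and 4127 genes for the same tumours at an adjusted p under 0.05. Fold changes in the authors' deposited tables and in edgeR correlated at 0.984 to 0.991 across genes, which are not independent replicates. The spread in these fits came from the untreated tumours alone, and without untreated tumour 1 the counts rose to between 6132 and 9247, while without untreated tumour 2 that of resistant tumour 4 was 1738.

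Set against the other resistant tumours, resistant tumour 4 had 475 genes called higher and 55 lower in edgeR. PMEL, a gene of pigment granules, was at 501.8 CPM in resistant tumour 4, 0.76 ± 0.24 CPM in the other 4 and 0.87 CPM on average in untreated tumours (log2 fold change 9.37, SE 0.22, edgeR adjusted p = 5.63e-08). CPXM1 and FGFBP2 were at 50.9 and 36.8 CPM there, and at 0.16 ± 0.20 and 0.12 ± 0.15 CPM in the others. STAC, ODZ2 and ASTN1 were lower in resistant tumour 4, at 10.5, 10.5 and 3.82 CPM against 34.5 ± 6.34, 57.1 ± 25.7 and 27.1 ± 13 CPM. Resistant tumour 5 had 10 genes higher and 1 lower. FOXP1, a forkhead transcription factor gene, was at 109 CPM there against 1.66 ± 1.42 CPM (edgeR adjusted p = 0.0108), GRIP1 at 31.4 against 1.61 ± 0.63 CPM, PCDH15 at 73.7 against 3.96 ± 1.38 CPM, and TFAP2C at 5.67 against 23.1 ± 4.06 CPM. In resistant tumour 3, the cholesterol synthesis genes HMGCS1 and IDI1 were at 171 and 84.5 CPM against 50.3 ± 6.68 and 35.5 ± 3.84 CPM, and RASAL2 at 109 against 55.4 ± 4.49 CPM, with edgeR adjusted p of 0.0105, 0.0461 and 0.0494. Resistant tumours 1 and 2 had 0 genes called by edgeR, and 1125 and 607 at an unadjusted p under 0.05. At that unadjusted threshold, chance alone would give a share of about 0.05 of the 16655 tested genes, more than resistant tumour 2 had. No other tool was run on these comparisons. With the 5 resistant tumours alone, 69 genes were called for resistant tumour 4, without STAC, ODZ2 and ASTN1 (edgeR adjusted p 0.101 to 0.267), and 0 for resistant tumours 3 and 5. Leaving out single libraries ended the calls of ASTN1 (untreated tumour 2, 3 or 4), ODZ2 (any untreated tumour or resistant tumour 3), TFAP2C (any untreated tumour), HMGCS1 (untreated tumour 2 or 3), IDI1 (any untreated tumour or resistant tumour 2 or 5) and RASAL2 (any untreated tumour or resistant tumour 1 or 2), at edgeR adjusted p of 0.0536 to 0.213. The count of resistant tumour 4 was 339 without untreated tumour 2, 348 without untreated tumour 4 and 1182 without resistant tumour 2, and those of the other tumours ranged from 0 to 154 when single libraries were left out.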

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

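Of the tests in this part, those of thinning, of the untreated range, of other splits and of the collagen genes with the GC trend removed were fixed before their results were seen, and those of genes nearly lost in other tumours and of fibroblast markers called lower were chosen after the result was seen. A sample counts here as far from its group when its gap to the nearest other sample takes up most of the group's range, judged by Dixon's ratio on log2 CPM. In 316 groups of values, 30 such samples were found. Of these, 9 were among the resistant values of 13 genes that had been named because a single resistant tumour differed, so their distance follows from that choice. In the other 303 groups there were 21, where chance gives about 15.2.

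Untreated tumour 1 was the far sample for 11 genes. It was lowest for KITLG (ratio 0.853), LIPE (0.915), BAX (0.86), MCM5 (0.833), LOXL2 (0.853), TM7SF2 (0.858) and TNFAIP2 (0.881), and highest for TIMP1 (0.924), LEF1 (0.92), RASA2 (0.844) and S100A1 (0.883). In this library the bin of genes with the highest GC content lay at -0.42 on the log2 scale relative to the mean of all libraries, against -0.14 to 0.17 in the other 8. Of the other untreated tumours, the number 2 was lowest for KSR2 (0.83), number 3 was highest for MKX (1) and AXL (0.835), and number 4 was highest for PAMR1 (0.955). MKX had 0, 0, 4 and 0 reads in untreated tumours 1 to 4, and PAMR1 2, 1, 1 and 5 reads. Their ratios rest on counts near the floor of 3 reads and say little. Among resistant tumours, number 2 was highest for HLA-DRA (0.795) and HLA-DPA1 (0.755). Number 3 was highest for IDI1 (0.756), RASAL2 (0.749), HMGCS1 (0.771) and ABCG2 (0.914). Number 5 was lowest for TFAP2C (0.748) and highest for PCDH15 (0.758) and GRIP1 (0.758).

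Resistant tumour 4 was highest for PMEL (0.892), CPXM1 (0.767), FGFBP2 (0.756) and LEF1 (0.911) and lowest for EMR1 (0.773) and TNFAIP2 (0.837). Its library was the deepest, but with its reads thinned to 18953117 the count of genes called against the other resistant tumours was 526, beside 530 at full depth, which argues against depth. Cells like those of the untreated tumours mixed into it cannot lift a gene above both parts of the mixture, yet 66.9% of the 475 genes called higher, 318 genes, lay above the highest untreated tumour. For the remaining genes such cells may still contribute: such a mixture would hold 16 genes nearly lost in the other resistant tumours at a common fraction of their untreated level. Across these genes the 10th percentile of that fraction was 24.6% of its median, with a bootstrap interval of 0 to 67% that was added after the value was seen and is too wide to decide. A difference in lineage state between resistant tumours stays open and was not tested, since the labels give no group within them.

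COL1A1 and COL3A1 rose while DCN, LUM and PDGFRA fell. The collagen gene COL1A2, named after its values were seen, was not called (log2 fold change 0.995, edgeR adjusted p = 0.309). It was at 133, 202, 92.7, 1161 and 291 CPM in resistant tumours 1 to 5, and at 89.2 to 253 CPM in untreated tumours. If all these markers came from unchanged host fibroblasts, more such reads would raise them together. Instead, 3 fibroblast markers were called lower, with DCN, named after its values were seen, at a log2 fold change of -2.67. Those falls were part of the pattern itself, and which cells gave each marker's reads is not known. The count therefore cannot decide, and more host reads stay open for COL1A1 and COL3A1. GC content does not account for the rises, since 100% of the 5 markers called higher were still called higher with the GC trend removed. A change in the state of fibroblasts or expression of COL1A1 and COL3A1 by the tumour cells stays open and was not tested.

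The count of 4861 genes called between resistant and untreated tumours was reached by 1 of 100 drawn splits of the 9 samples, the real one, and the highest of the others was 221. The real split is always counted, so 1 of 100 was the lowest share possible. Chance is unlikely for that count but not excluded. Every other split mixes the 2 groups, which widens the spread within groups, so the size of the gap adds nothing to this.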

How the results depend on the processing

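The GC correction was chosen after seeing the data, and the other settings were fixed before the data were examined. Counts of genes called between the groups stayed within 1.5 times of 2433 and 2428 under other size factors, library sizes, filters, tools, the GC correction and each left-out library, with 47.09 to 53.16% of the calls higher. Stricter thresholds, by construction, left 1125 and 1232 genes (adjusted p under 0.01) or 907 and 824 (2-fold). Of the comparisons of named genes with an alternative, 2817 kept direction and side of the threshold, 97 lost the call, 39 gained it and 10 changed sign. Part of the 97 losses came from the stricter thresholds, by construction. At an adjusted p under 0.01, resistant tumours 1 to 5 had 2255, 1616, 3395, 1347 and 2145 genes called against untreated tumours, and numbers 3, 4 and 5 had 0, 204 and 4 against the other resistant tumours. With resistant tumours alone, and so fewer samples, these 3 counts were 0, 69 and 0, and with the 1 CPM filter resistant tumour 2 had 1 such gene. When each library was left out, counts against untreated tumours ranged from 3093 to 7439, 2322 to 6788, 4562 to 9247, 1738 to 6132 and 2953 to 7980, lowest without untreated tumour 2 and highest without untreated tumour 1 for each. Against the other resistant tumours the ranges were 0 to 13, 0 to 154, 0 to 11, 339 to 1182 and 7 to 58. With an estimated correlation 0 lists were called by camera, at adjusted p of 0.5622 (ERK output, cell cycle, hypoxia and glycolysis, oxidative phosphorylation, p53 targets, mitochondrial transcripts) or 0.7742 (interferon response, antigen presentation). Leaving out libraries gave 0.0003802 to 0.1278 for antigen presentation and 0.02412 to 0.1278 for hypoxia. Lists far from the threshold turned direction: receptors, matrix and endothelial markers with the GC trend removed (0.9996), and these, drug transport and the BCL2 family without some libraries (0.7392 to 0.9896). In the comparison of the groups limma-voom with sample weights turned CPXM1, FGFBP2 and PCDH15 to log2 fold changes of -1.62, -2.736 and -0.312. Without single libraries the log2 fold change spanned -0.202 to 7.195 for PMEL, -2.615 to 3.694 for CPXM1, -3.685 to 2.559 for FGFBP2, -0.932 to 1.509 for PCDH15 and -0.238 to 0.204 for TNNC2. Of the left-out libraries, PMEL, CPXM1 and FGFBP2 were negative only without resistant tumour 4, and PCDH15 only without resistant tumour 5. Group differences of small library measures also changed sign: total count -2.722 to 3.816 (1e6 reads), share of the 10 most abundant genes -0.2505 to 0.0655 percentage points, endothelial score -0.3475 to 0.09921 and leukocyte score -0.2661 to 0.005882. The cause of these shifts was not tested, beyond the stricter thresholds, which lower counts by construction. Using the resistant tumours alone changes both the number of samples and which tumours give the spread. Depth limits genes with 3 or fewer reads in a group, whose ratios have wide counting intervals.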

Other observations

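The tests of GC content here were fixed before their results were seen, and that of windows was chosen after the result was seen. Genes of chromosome 18 were higher in resistant tumours 1, 3 and 5, while their median difference was small in resistant tumours 2 and 4. Over its 259 tested genes, the median log2 difference from the untreated mean was 0.59, 0.64 and 0.63 in the first 3 of these tumours, and 0.10 in each of resistant tumours 2 and 4. Medians of all chromosomes in untreated tumours, each against the other untreated tumours, lay between -0.19 and 0.11. Of 10000 random lists of as many genes, 0.12% and 0.07% had a median as high as that of chromosome 18 in resistant tumours 2 and 4. Such lists do not allow for genes of a chromosome moving together, and none were drawn for untreated tumours. Untreated tumour 1 was at 0.086 on chromosome 18. With the GC trend removed resistant tumours 2 and 4 were at 0.13 and 0.11, and untreated tumours between -0.04 and 0.04 over all chromosomes. Resistant tumour 4 was then as far from 0 on other chromosomes, at 0.15, 0.14 and -0.13 on chromosomes 22, 7 and 9. Before that correction, chromosome 13 was at -0.42, -0.30, -0.25, -0.04 and -0.18 in resistant tumours 1 to 5, and chromosome 20 at -0.29 in resistant tumour 5. After it, chromosome 13 was at -0.39, -0.25, -0.35, -0.02 and -0.27 in these tumours, and chromosome 20 at -0.26 in resistant tumour 5.

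The chromosome 18 pattern was not removed by correcting for GC content, after which the lowest median in resistant tumours 1, 3 and 5 was 0.54 (0.539 before rounding). Each of the 10 Mb windows with at least 10 genes had a median above 0 in these 3 tumours, from 0.31 to 0.81. The rise was therefore not confined to a single part of the chromosome. A step from 2 to 3 copies would give 0.59 and a step from 3 to 4 copies 0.42. Extra copies of the whole chromosome may underlie the pattern. Regulation along it could also put every window above 0, given the chromosome medians already seen, so the windows cannot decide between these. In resistant tumours 2 and 4 the window from 30 to 40 Mb was at -0.16 and -0.19, and their other windows were above 0. Resistant tumours 1, 3 and 5 had the lowest SOX10 and ERBB3 levels. No relation between these was tested. Copy number was not measured in the data used here, and regulation along the chromosome stays open.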
